A study of Mus musculus with 2 samples.

How the data were processed

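Liver RNA of CD1 mice, an outbred stock, was compared after exposure in utero to a control or a high fat maternal diet. Per the labels' protocols, total RNA was extracted with TRIzol from 6 control and 7 high fat livers, pooled within each diet, converted to double-stranded cDNA and labelled by the array maker, NimbleGen. Each diet is therefore represented by 1 pooled sample, and the spread between animals was lost at the pooling step. Per the labels, the control pool carried Cy5 and the high fat pool Cy3, with no dye swap among the samples used here, so diet and dye cannot be told apart. The series' description speaks of 2 chips, whereas the different dyes would also allow both pools on 1 array, and the sources used here do not settle which was done. The age and sex of the mice are not given in the labels used here.

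The deposited intensity values, 1 per sequence identifier and pool, are named RMA values in the authors' files. RMA is a procedure that corrects background, normalizes arrays and summarises the spots of a target into 1 value. The steps, the software version and the genome build behind the identifiers are not given in the sources used here. The values lie on a linear scale and range from 11.1 to 64710, so their log2 was taken here. A further table of the series holds values identical to those of the sample files for all 32650 identifiers, and it therefore adds no independent measurement. The authors' files also hold a column named as an error of each value. It lies between 0.594 and 0.998, rises with the intensity (Spearman's rho across identifiers 0.97 in both pools) and reads -99 for 34 identifiers. Its scale is not stated, and it was not used as an error.

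The identifiers are those of the array's design, and 0 of them matched the gene table of the reference used here (GRCm38.p6). No gene symbol, position or annotation is therefore reported, and the 41 gene lists that had been fixed before the data were examined were not tested. Several identifiers may belong to 1 gene, so counts are counts of identifiers.

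The log2 ratio of the high fat over the control pool was computed for each identifier. A random-sequence control feature was kept out of all counts and used as a measure of background. The planned filter on low values used odorant receptor genes, which the absence of symbols ruled out. Its planned replacement was applied, namely that an identifier be above the pool's median over all identifiers in at least 1 pool, which kept 16797 identifiers. Identifiers with at least a 2-fold difference were counted as a rule of size. No p-value was computed, because 1 sample per group gives no estimate of the spread between samples. The spread of log2 ratios across identifiers was given as the robust SD, 1.4826 times the median absolute deviation. As a point of reference, a normal distribution with the median and robust SD of the log2 ratios was drawn 100 times. By the rule for named items, the 2 highest and 2 lowest identifiers are named.

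The alternatives were a lowess correction of the log2 ratio on the mean level (span 0.4), centring on the median, quantile normalization, other filters, thresholds of 1.5-fold and 3-fold, and 50 added to both values before the logarithm. The calculation was tested on simulated data with 200 of 32650 identifiers changed for the high fat over control comparison. After the lowess correction, 91% of those changed by 1.5 on the log2 scale and 100% of those changed by 3 were called. The changed identifiers were drawn from those that pass the filter, and the noise was normal with the same SD for all identifiers. These shares describe recovery under those conditions only. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Array files give no read depth, and the single measurement per pool limits the precision.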

Results

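Hepatic RNA levels were measured by NimbleGen expression array in 2 pools, 1 from 6 livers exposed to a control diet in utero and 1 from 7 livers exposed to a high fat diet in utero. Each pool gave 1 intensity for each of 32650 sequence identifiers. The median intensity was 399 in the control pool and 431 in the high fat pool, and the middle 50% of values spanned 51.1 to 2410 and 52.2 to 2492, respectively. The random-sequence control feature, a measure of background hybridisation, read 24.3 in the control pool and 22.8 in the high fat pool. Intensities at or below that control were found for 6.04% of identifiers in the control pool and 5.46% in the high fat pool. The 1000 brightest identifiers held 31.7% of the summed intensity in the control pool and 31.4% in the high fat pool.

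The comparison asked whether a high fat diet of the mother during pregnancy altered hepatic gene expression in the offspring. Most transcripts were at similar levels in both pools, and the larger differences were mainly toward higher levels in the high fat pool. Of the 16797 identifiers above the median in at least 1 pool, 268 were at least 2-fold higher and 92 at least 2-fold lower in the high fat pool. At least 4-fold differences were seen for 98 higher and 3 lower identifiers. At least 8-fold differences were seen for 38 higher and 0 lower identifiers, and 20 of the higher ones reached 16-fold. The control value lay within 4 times the random-sequence control for 21 of those 38 and 15 of those 20. With both pools required above their median, a setting chosen after seeing the data, 34 identifiers were at least 4-fold higher and 3 lower, and 5 were at least 8-fold higher and 0 lower. Differences within 1.5-fold in either direction accounted for 88.2% of the 16797 identifiers. There was 1 pool per diet, so none of these differences has a replicate check, and dye and diet coincided.

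**Figure D1:**
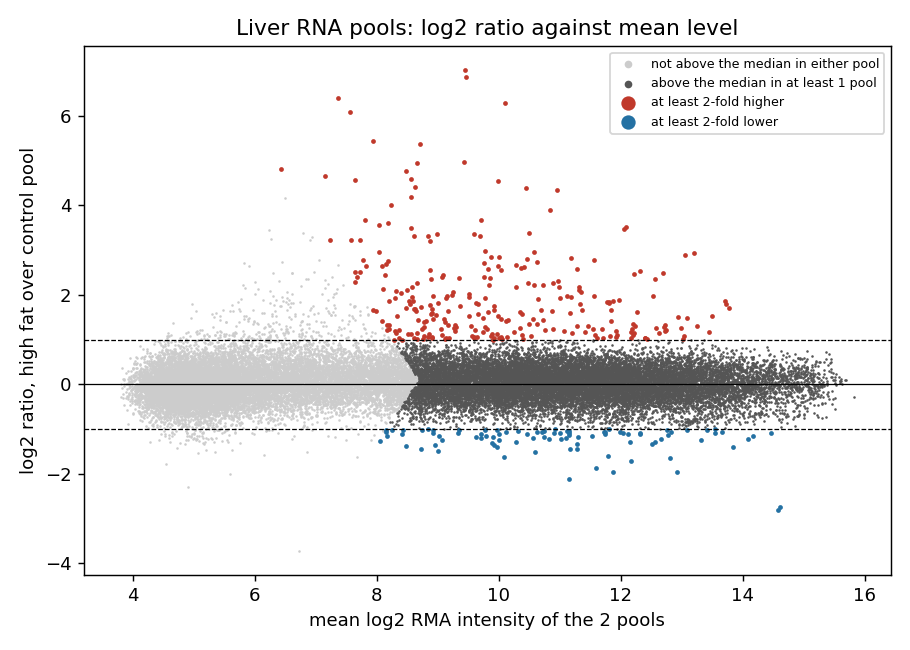
Log2 ratio of RMA intensity, high fat over control pool, against the mean log2 intensity of both pools, with 1 point per sequence identifier. Dashed lines mark a 2-fold difference; the 268 red points above the upper line reach a log2 ratio of 7.02, whereas the 92 blue points below the lower line reach -2.81, at the highest control value.

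The highest ratio toward the high fat pool was that of identifier MMUS0407S00002494, which read 60.9 in the control pool and 7902 in the high fat pool, a log2 ratio of 7.02. Identifier MMUS0407S00032442 read 64.9 and 7601, a log2 ratio of 6.87. In the control pool, both values were under 4 times the random-sequence control, so that the size of both ratios rests on a control value close to background. The lowest ratios were those of MMUS0407S00029665, which read 64710 in the control pool and 9210 in the high fat pool, and MMUS0407S00035285, which read 64710 and 9674. Their log2 ratios were -2.81 and -2.74. Both identifiers held the same control value, the highest in that pool and shared by no other identifier. If that value is the ceiling of the scale, the differences of 7.03-fold and 6.69-fold are lower bounds and their rank is not settled. Gene names and genomic positions of these identifiers were not analysed here.

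The 268 identifiers at least 2-fold higher in the high fat pool had a median intensity of 427 in the control pool and 1676 in the high fat pool, and 127 of them were at or below the control pool's median of 399. The 98 identifiers at least 4-fold higher had median intensities of 234 and 2055, and 64 of them were at or below 399 in the control pool. The 38 identifiers at least 8-fold higher had median intensities of 84.8 and 1728, and 33 of them were at or below 399 in the control pool. Because the control value is the denominator of the ratio, a stricter fold threshold by itself selects lower control values. Of the 92 identifiers at least 2-fold lower, 17 were at or below the median of the high fat pool. An identifier low in 1 pool passes the filter only if it is above the median in the other.

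**Figure D2:**
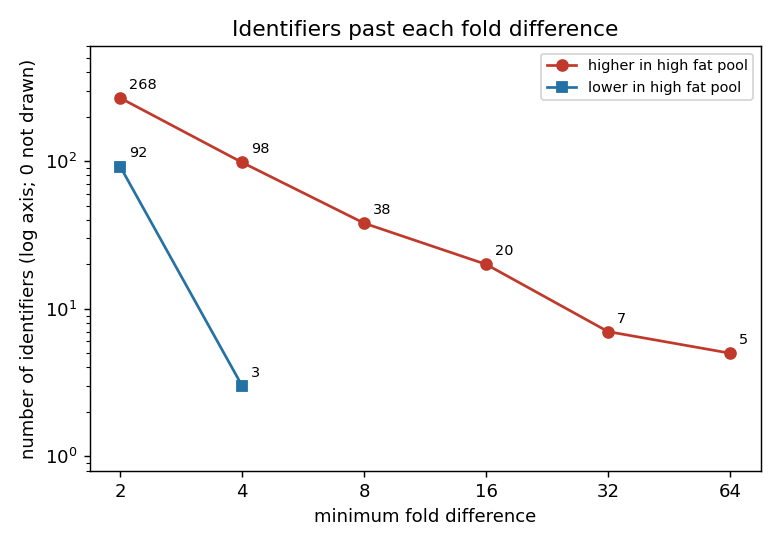
Number of identifiers (log axis) at or beyond each minimum fold difference, among the 16797 above the median in at least 1 pool; circles are higher and squares lower in the high fat pool. Higher identifiers number 268 at 2-fold and 5 at 64-fold, whereas lower identifiers number 92 at 2-fold, 3 at 4-fold and 0 at 8-fold.

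The excess of higher identifiers was greatest among transcripts of low mean level. The 16797 identifiers were ranked by mean intensity and cut into 4 bands of equal size. In the lowest band, 150 were at least 2-fold higher and 27 at least 2-fold lower. In the second band, these numbers were 51 and 27, and in the third 45 and 18. In the brightest band, 22 were higher and 20 lower. The median log2 ratio was 0.06 in the lowest band and 0.0086 in the brightest, and the robust SD was 0.41 and 0.35, respectively. The filter asks for 1 pool above its median, so that an identifier of the lowest mean levels passes it only when the pools differ. With both pools required above their median, 141 identifiers were at least 2-fold higher and 75 at least 2-fold lower.

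Across the 16797 identifiers, the log2 intensities of the pools correlated with a Pearson's r of 0.962, an association across identifiers that are not independent replicates. The median log2 ratio was 0.04, with an SD of 0.46 and a robust SD of 0.37. Among the 15853 identifiers above the median in neither pool, the robust SD was also 0.37. A 2-fold difference therefore equalled 2.71 robust SDs of the log2 ratios. A normal distribution with that median and robust SD gave on average 73.6 identifiers at least 2-fold higher and 41.5 at least 2-fold lower, against the observed 268 and 92. At 4-fold, it gave 0.01 higher and 0 lower, against 98 and 3. The draws were independent and used the same SD at all levels, so they do not represent measurement error with heavier tails. The excess over them therefore does not separate measurement error from a difference between the diets. The robust SD covers the differences between identifiers in 1 measurement of each pool, and not the variation between mice.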

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

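The excess of higher over lower identifiers held under each alternative that was run, and its size depended on the filter, the threshold and the scaling. The 360 identifiers past 2-fold (268 higher, 92 lower, 74.4% higher) became 759 (566 and 193) with no filter and 162 (108 and 54, 66.7% higher) with at least 1 pool above the 75th percentile. A 1.5-fold threshold gave 1987 (1117 and 870, 56.2% higher), and a 3-fold threshold gave 159 (149 and 10, 93.7% higher). The share of higher identifiers was 69.55% after the lowess correction, 68.7% after centring and 67.0% after quantile normalization, with total counts of 358, 364 and 361. With 50 added to both values, the robust SD was 0.357 instead of 0.369, and the log2 ratios of MMUS0407S00002494 and MMUS0407S00032442 were 6.16 and 6.06, since the added value weighs most on low intensities. Elsewhere the log2 ratios of the named identifiers moved by less than 1 robust SD where they stayed in the set; the 2 highest dropped out with both pools required above their median, and the 2 lowest when identifiers at the highest control value were left out. The following alternatives were chosen after seeing the data. Requiring both pools above their median gave 216 identifiers (141 higher, 65.3% of the total) with a robust SD of 0.354, and lowered the count of 4-fold higher identifiers from 98 to 34 and of 8-fold higher ones from 38 to 5. Requiring at least 1 pool at 4 times the random-sequence control gave 598 (486 higher, 81.3%). Leaving out identifiers without an error value or at the highest control value gave totals of 359 and 358. The table of the series gave the same values. The receptor-based filters, the brightest identifier per gene and the gene lists were not run, because they need gene symbols. No paired analysis was possible because each diet has 1 pooled sample. Intensities near the random-sequence control limit the ratios of the scarcest transcripts.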

Other observations

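Of the tests below, the one on neighbours with different mean levels was set out before its result was seen, and the others were chosen after the patterns had been seen.

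Large differences ran almost entirely toward the high fat pool. After the lowess correction, 95 identifiers were 4-fold higher and 3 were 4-fold lower, a ratio of 31.7. The correction removes only a trend with mean level that most identifiers share. That trend was small, with a median log2 ratio of 0.06 in the lowest band of mean level and 0.0086 in the brightest. Such a shared trend is therefore argued against as the whole cause. The correction cannot test a dye difference confined to some identifiers. The excess was not confined to values near background. With both pools above their median, 34 identifiers were 4-fold higher and 3 were 4-fold lower. These identifiers were selected to lie away from background, so their counts are no test of noise near background. The counts do not speak for the 64 of the 98 whose control value was at or below the control pool's median. For the 28 of the 98 whose control value lay within 4 times the random-sequence control, it stays open how far the size of the ratio reflects noise, because 1 value per pool offers no repeat. The maternal diet, a sequence-specific dye difference, RNA of another tissue in the high fat pool and a single deviating liver among the 7 remain open as hypotheses, and none was tested, since this needs gene names, a dye swap or individual livers.

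Identifiers next to each other in file order had similar log2 ratios. Spearman's rho between successive identifiers above the median in at least 1 pool was 0.389, against a highest value of 0.0236 in 1000 shuffles of the order, and it fell to 0.0980 at a distance of 20 such identifiers and 0.0017 at 1000. Of the 98 identifiers at least 4-fold higher, 52 lay directly next to another, against a mean of 0.736 for random draws. The lowess correction left rho at 0.389, so a trend with mean level shared by most identifiers did not produce it. That trend was small, and the correction cannot test a dye difference confined to some identifiers. A candidate explanation is that the order places identifiers of the same or closely similar RNAs together. For neighbours at least 4-fold apart in mean level, it predicted a rho under 0.1. A rho above 0.2 was set to speak against it. The 5032 such pairs gave 0.224 (95% bootstrap interval 0.197 to 0.251), and neighbours within 4-fold gave 0.46. The value was above 0.2, but its interval reached below, so the test did not decide. Pairs were resampled as if independent although successive pairs can share an identifier, so the interval may be too narrow. Spots of 1 RNA can also differ in brightness, so the explanation cannot be told apart from neighbours with shared regulation. Similar log2 ratios also reached further in the order than similar mean levels. At a distance of 5 such identifiers, rho was 0.151 for log2 ratios and 0.0036 for mean levels. The counts above may still stand for fewer separate genes.

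All 34 identifiers without a deposited error value were lower in the high fat pool, with a median log2 ratio of -0.75 and a range from -1.08 to -0.32. The median was -0.76 after the lowess correction, so a trend with mean level shared by most identifiers did not produce it. A dye difference that acted on these 34 alone was not tested by the correction, and dye and diet coincided. All 34 values in both pools fell on a grid of steps of 0.005, against 3.18% of the other identifiers in the control pool and 3.31% in the high fat pool, and 26 had control intensities between 10000 and 14000. These features are consistent with values that were not summarised over several spots, and possibly with a shared sequence or a control target, which was not tested; 1 of the 34 was among the identifiers at least 2-fold lower.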
